A study of Mus musculus with 12 samples.

How the data were processed

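The series holds 12 mouse libraries in 4 groups of 3. In liver, 3 libraries came from mice given carbon tetrachloride (CCl4), a solvent that injures hepatocytes, and 3 from mice given vehicle, all sequenced as bulk RNA. In dorsal skin, 3 libraries came from CCl4-treated mice and 3 from vehicle-treated mice, made by smart-seq, a full-length cDNA method for small amounts of RNA, from CX3CR1+ cells of a Cx3cr1-creER:Ai9 reporter strain. The submitters' design text describes 3 biological replicates per group and speaks of hepatocytes, whereas the sample labels say liver, so the material is called liver here. Dose, time after injection, sex and age of the mice are not given in the sources used here. The labels give 1 extraction and library protocol for all 12 libraries, with poly(A) selection from bulk RNA, which does not describe the smart-seq libraries. How the skin cells were sorted or counted is not given in the sources used here.

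The authors deposited 1 table of TPM (transcript abundance scaled for length and library total) for 57180 genes and 12 libraries, all of whose columns matched a sample label. Reads had been processed with fastp, HISAT2, StringTie and RSEM against GRCm39, per the submitters' processing notes, which give neither versions nor the role of each tool in the TPM values. TPM divides each gene's signal by transcript length and scales every library to the same total, so the values hold no sequencing depth: depth is unknown, no counting interval can be given, and a gene that takes a larger part of a library lowers all others. A value of 0 can be a failed estimate, so such genes are described as listed at 0. No pair of columns was identical. Of the 57180 gene IDs, 51884 had a symbol in the name tables and 5296 did not; 66 IDs carried a symbol that another ID with a higher mean also had and were left without it. The reference annotation at hand is GENCODE M21 on GRCm38, another build than that of the table, so it served for transcript sequences only and no coordinates are given.

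Values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1. Fold changes are CCl4 minus vehicle on that scale, which understates changes of genes with low TPM. Liver and skin were fitted separately, because assay and strain differ between them. Genes with a TPM of at least 1 in at least 3 of the 6 libraries were tested with lmFit and eBayes (trend on mean expression), two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene is limma's. Effects in the 2 tissues were compared in 1 limma model of 4 group means over all 12 libraries, over genes that passed the filter in both tissues. Single values were compared by two-sided exact permutation tests, whose smallest possible p with 3 libraries against 3 is 0.1.

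Gene lists were fixed before the data were examined: 28 lists by function and 24 lists of cell type markers, of which 35 applied to liver and 37 to skin. Of their members, 6 had no match in the table. Lists with at least 4 measured members were tested with limma's camera, which asks whether a list's genes moved up or down relative to all other genes. The correlation between genes was preset at 0.01, and p was adjusted over the lists of a tissue. Each list was also tested with a correlation estimated from the data and with fry, a rotation test of whether the list's genes moved on balance in 1 direction. Counts of members that rose or fell use the adjusted p over all genes tested, with the count adjusted over the list alone beside it where it differs. A listed gene near 0 TPM in 1 group is measured only if the other group takes it past the filter, so such counts lean towards change.

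Genes were named by a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls among called genes whose groups do not overlap and whose mean TPM is at least 5, leaving out clones, predicted genes and pseudogenes. Where no gene was called, it takes the 8 lowest p in each direction as values only. It adds up to 4 members with the lowest p of each list called by camera, and a set of genes chosen in advance: Mdk, Ptn, Lrp1, Ptprz1, Sdc4 and Cx3cr1 in both tissues, Cyp2e1, Alb, Cyp7a1 and Col1a1 in liver, and Csf1r, Cd207, Mrc1 and Il1b in skin. Other genes are said to be chosen after their values were seen.

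Alternatives chosen at that time were pseudocounts of 0.1 and 5, no filter beyond a TPM above 0, a filter at a TPM of 5, and 3 other scalings: median-ratio scaling, quantile normalization, and TPM rescaled after leaving out mitochondrially encoded genes and the 10 most abundant genes. Further ones were a replicate block, 1 fit over all 12 libraries, robust eBayes, an added minimum log2 change of 1, and leaving out each library in turn. Alternatives added after seeing the data were TPM rescaled without mitochondrially encoded genes and 11 pseudogenes that are near copies of them, library number 1 of the skin groups as a batch term, and both skin libraries numbered 1 left out. Near copies were pseudogenes of GENCODE M21 with at least 95% identity to a mitochondrial mRNA over at least 80% of their length. A call is said to hold under the scalings when it passed in the same direction under all of the 3 scalings that kept the gene; mitochondrially encoded and top genes are left out of the rescaled values.

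The procedure was tested on data simulated from each tissue's own means and spreads, with 50 genes changed at each of 4 sizes. In liver, over 10385 genes, it recovered 42% of genes changed by 1 on the log2 scale, 76% at 2, 96% at 3 and 100% at 4, with 11 false calls. In skin, over 13767 genes, it recovered 0% at 1, 0% at 2, 18% at 3 and 46% at 4, with 0 false calls. Noise was drawn independently for each gene, and changed genes had a mean above 2 in log2(TPM + 1). The recovery thus does not cover genes of low TPM, nor do the false calls cover noise shared between genes. The median residual SD of a gene was 0.28 on the log2 scale in liver and 0.83 in skin.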

Results

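Gene expression was measured in liver and in dorsal skin CX3CR1+ cells of mice given CCl4 or vehicle, with 3 libraries in each of 4 groups. CX3CR1, the fractalkine receptor, is carried by monocytes, macrophages and some other immune cells. The series title names midkine, a secreted heparin-binding growth factor encoded by Mdk, and itch evoked by light touch. The comparisons therefore asked which transcripts differed with CCl4 in liver, which differed in the skin cells, and whether the effects differed between both. All values are TPM as deposited, which hold no read depth. Liver libraries listed 17568 to 17828 genes above 0 with vehicle and 19473 to 20757 with CCl4 (exact permutation p = 0.1, the smallest possible, n = 3 per group). In skin, the libraries numbered 1 listed 28870 genes above 0 with vehicle and 28357 with CCl4, against 21328 to 23494 in the other 4 libraries.

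Mitochondrially encoded transcripts took a much larger part of the liver libraries after CCl4. Genes with a mitochondrial (mt-) symbol, among them the 13 measured that encode subunits of the respiratory chain, held 18.0% ± 1.22 of the TPM with vehicle. They held 53.1% ± 5.68 with CCl4 (mean ± SD, n = 3 per group, exact permutation p = 0.1). With the 11 near-copy pseudogenes, the shares were 26.7% ± 1.51 and 76.8% ± 7.60 (n = 3 per group, exact permutation p = 0.1), as the plot of mitochondrial shares shows. All other genes together held 73.3% of the TPM with vehicle and 23.2% with CCl4, a log2 change of -1.71. The 10 most abundant genes of each library held 33.9% ± 0.686 with vehicle and 66.1% ± 6.14 with CCl4. In skin, mitochondrially encoded genes held 2.20% ± 0.609 with vehicle and 1.60% ± 1.07 with CCl4 (n = 3 per group, exact permutation p = 0.5).

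**Figure D1:**
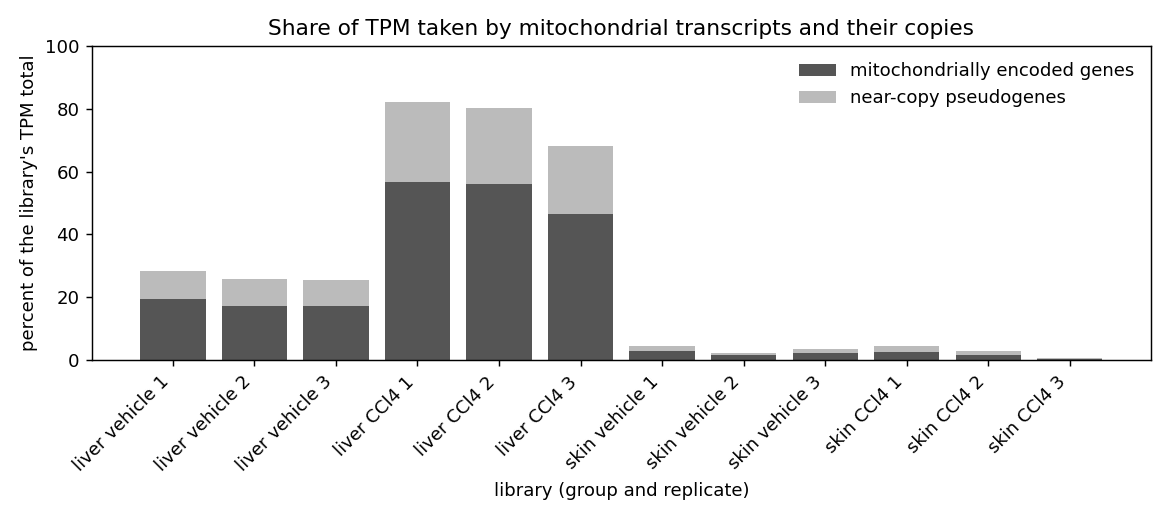
Percent of each library's TPM total (y axis) held by mitochondrially encoded genes (dark) and their near-copy pseudogenes (light) in the 12 libraries (x axis, group and replicate). Together they hold 68.1 to 82.1% in the liver CCl4 libraries and 25.7 to 28.4% in the liver vehicle libraries.

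In liver after CCl4, transcripts of hepatocyte metabolism, plasma protein synthesis and drug metabolism were lower in TPM as deposited, while transcripts of inflammation, matrix, proliferation and non-parenchymal cells rose. No liver list passed camera with an estimated correlation (smallest adjusted p = 0.131), whereas fry called 19. Without mitochondrial genes and copies in the total, 7 lists of hepatocyte functions with 182 members had a median change of -0.17 in place of -1.83, with 55 members lower in place of 159, and 30 higher. The median of all genes was then 0.85. The largest rises were Sprr1a, a cornified envelope protein, to 109 ± 36.4 TPM from 0.07, 0 and 0 in the vehicle libraries, and the neutrophil calprotectin genes S100a9 and S100a8, by 5.78 ± 0.59 and 5.18 ± 0.64 (log2 ± SE). Cyp1a1, a target of the aryl hydrocarbon receptor, rose from 0.597 ± 0.181 to 43.0 ± 10.9 TPM, a log2 change of 4.76 ± 0.25 (adjusted p = 5.16e-07). Anxa2 (annexin A2), Lyz2 (lysozyme of myeloid cells), Mmp12 (macrophage elastase) and S100g (calbindin D9k) rose by 4.38, 4.11, 4.07 and 3.97. Of the 8 largest falls, 7 were major urinary protein genes: Mup7 fell from 43118 ± 647 to 549.8 ± 172 TPM and Mup19 from 7068 ± 1613 to 8.38 ± 3.78 TPM. Mup17, Mup15, Mup1, Mup12 and Mup21 changed by -9.31, -7.82, -6.34, -6.10 and -5.68. Mup genes are near-identical paralogs that share reads, so their single values are uncertain. Elovl3, a fatty acid elongase, fell from 284 ± 125 to 3.43 ± 0.993 TPM, by 5.93 ± 0.36 on the log2 scale. All 16 genes kept their call under the 3 other scalings.

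Of 10385 genes tested in liver, limma called 6377, with 1073 higher and 5304 lower, so 16.8% were higher. The median log2 change of all genes was -0.59, and lists are therefore also given relative to that median. A single fit over all 12 libraries called 1736, with 334 higher and 1402 lower. Under median-ratio scaling the split was 2159 higher and 2210 lower, under quantile normalization 1826 and 2507, under rescaling without mitochondrial and top genes 6497 and 495, and under rescaling without mitochondrial genes and copies 6922 and 435. The calls that held under all 3 planned scalings were 1036 higher and 491 lower. Adding a minimum log2 change of 1 left 834 higher and 2873 lower. CCl4 and vehicle libraries did not overlap for 7291 genes, 70.2% of those tested, where chance gives 10%.

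**Figure D2:**
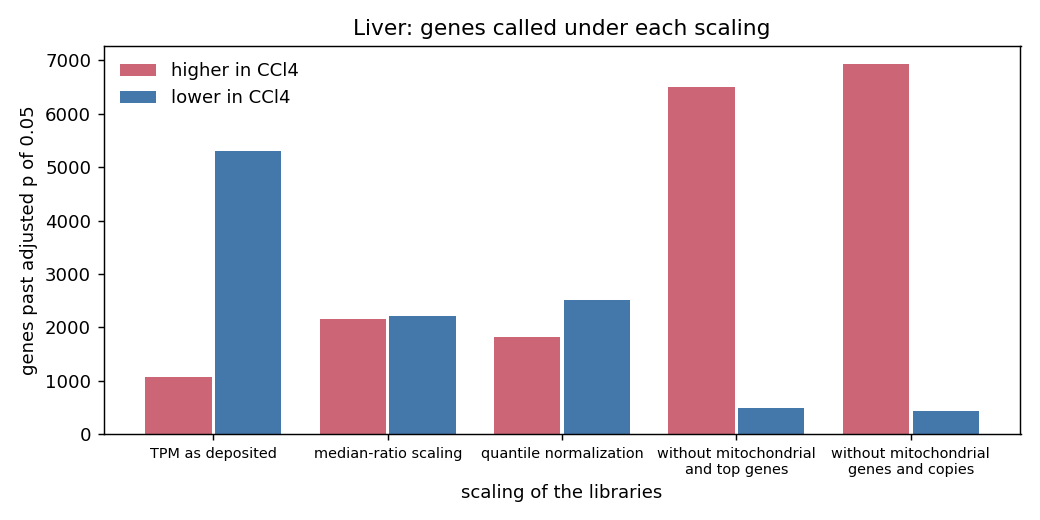
Number of liver genes past an adjusted p of 0.05 (y axis) that were higher (red) or lower (blue) in CCl4 under each scaling of the libraries (x axis). Genes called lower number 5304 in TPM as deposited and 435 once mitochondrial genes and their copies are left out of the total.

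Zonated hepatocyte genes were lower in TPM on both sides of the lobule. Of 22 pericentral genes, which are expressed around the central vein, 18 fell and 4 did not pass, and 20 fell adjusted over the list alone. Their median was -1.59, against -0.59 for all genes (camera adjusted p = 0.000485; adjusted p = 0.661 with an estimated correlation). Oat (ornithine aminotransferase) fell from 155 ± 15.8 to 7.21 ± 0.397 TPM, by 4.24 ± 0.26. Slc1a2, a glutamate transporter, fell by 2.59 and Cyp2c54 by 3.66. Cyp2e1, the cytochrome that activates CCl4, fell from 2290.2 ± 227 to 130.1 ± 77.6 TPM, a log2 change of -4.32 ± 0.43 (adjusted p = 4.54e-05). Of 21 periportal genes 18 fell and 3 did not pass, with a median of -1.97, or -1.38 relative to all genes (camera adjusted p = 0.00155; adjusted p = 0.661 with an estimated correlation). Among them Etnppl fell by 2.74, and the urea cycle enzymes Arg1 and Ass1 by 2.30 and 2.63. The mean changes of the pericentral and periportal lists were -2.00 and -1.82, in the reverse order of their medians. The medians of both lists were -0.05 and -0.29 once mitochondrial genes and copies were left out of the total, with 7 and 9 members lower and 5 and 4 higher. Of the falls, 7 pericentral and 8 periportal ones held under the 3 other scalings, Ass1 not among them.

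Lists of bile acid, drug and lipid metabolism were lower in TPM too. Of 25 genes of bile acid synthesis and transport, 23 fell, 1 rose and 1 did not pass: the uptake transporter Slco1a1 fell by 3.56 and the sterol 12-alpha-hydroxylase Cyp8b1 by 4.05, while the basolateral efflux pump Abcc4 rose by 2.07. Of 27 genes of xenobiotic metabolism, 23 fell, 1 rose and 3 did not pass: Cyp1a1 rose, and Cyp2d9, Sult2a8 and Cyp2d10 fell by 3.42, 4.09 and 3.01. Of 24 genes of cholesterol synthesis 22 fell and 2 did not pass, among them Mvk by 2.28, Tm7sf2 by 2.79 and Nsdhl by 2.46. Of 28 genes of fatty acid oxidation and PPAR-alpha targets, 23 fell, 1 rose and 4 did not pass. Cyp4a32 fell by 2.22 and Angptl4 by 2.83, and the hormone gene Fgf21 rose by 1.32. The medians of these 4 lists relative to all genes were -1.27, -1.25, -1.31 and -1.28 (camera adjusted p = 0.00236, 0.00407, 0.000302 and 0.00446; adjusted p = 0.661, 0.662, 0.661 and 0.662 with an estimated correlation). Rescaled without mitochondrial genes and copies, their own medians were -0.28, -0.15, -0.34 and -0.27 in place of -1.86, -1.84, -1.90 and -1.87, with 10, 9, 8 and 4 members lower and 6, 4, 2 and 4 higher. The falls that held under the 3 other scalings numbered 10, 9, 8 and 7. With a filter at a TPM of 5 the xenobiotic list lost its call (camera adjusted p = 0.0590).

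Plasma protein and respiratory chain transcripts were lower in TPM. Of 35 genes of complement and coagulation, 32 fell and 3 did not pass, 33 adjusted over the list alone, and 8 falls held under the 3 other scalings. Coagulation factor F11, prekallikrein Klkb1 and complement C8b fell by 2.34, 2.21 and 2.34. Their median was -1.21 relative to all genes (camera adjusted p = 2.64e-05; adjusted p = 0.661 with an estimated correlation). Their median was -0.08 in place of -1.79 once mitochondrial genes and copies were left out of the total, with 8 members lower and 5 higher. Of 78 nuclear-encoded respiratory chain genes, 76 fell, 1 rose and 1 did not pass, with a median of -0.95 relative to all genes (camera adjusted p = 1.36e-06; adjusted p = 0.661 with an estimated correlation). Atp5s, Ndufa9 and Ndufa7 changed by -1.16, -1.95 and -1.73, and 0 of the 76 falls held under the 3 other scalings. After that rescaling the list's median was 0.15 in place of -1.53, with 0 members lower and 17 higher. All 13 mitochondrially encoded genes of respiratory chain subunits rose instead, 12 of them also under the other scalings that kept them. Their median was 1.60, or 2.18 relative to all genes (camera adjusted p = 6.58e-18, and adjusted p = 0.177 with an estimated correlation). Among them mt-Atp8 rose by 1.44, mt-Co1 by 1.60 and mt-Nd4l by 1.85. All 3 lost their calls without a filter on low TPM and in the fit over all 12 libraries, and mt-Atp8 also under quantile normalization, at 0.00.

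Matrix, proliferation and inflammation lists rose, with 20 of 32, 24 of 35 and 21 of 28 listed genes past the filter on low TPM. Of 20 genes of extracellular matrix and activated stellate cells, 19 rose and 1 did not pass, with Col3a1, Dcn (decorin) and Sparc up by 3.48, 3.60 and 3.84 (camera adjusted p = 1.19e-24; adjusted p = 0.177 with an estimated correlation). Of 24 cell cycle genes, 22 rose and 2 did not pass. Top2a, Ccnd1 and the kinase Cdk1 rose by 2.53, 2.78 and 3.55 (camera adjusted p = 4.01e-23; adjusted p = 0.177 with an estimated correlation). Of 21 inflammatory cytokines and NF-kB targets, 16 rose, 1 fell and 4 did not pass, and 18 rose and 1 fell adjusted over the list alone. The chemokines Ccl2 and Cxcl2 and the cytokine Il1a rose by 3.36, 3.54 and 3.14 (camera adjusted p = 3.89e-19; adjusted p = 0.131 with an estimated correlation). The medians of these 3 lists relative to all genes were 2.74, 2.52 and 2.23. Of 18 secreted growth factors, 9 rose, 5 fell and 4 did not pass (camera adjusted p = 0.000128; adjusted p = 0.153 with an estimated correlation). Hepatocyte growth factor Hgf rose by 2.68 ± 0.22, from 0.113 ± 0.0404 to 6.31 ± 2.05 TPM. Of 19 immediate early and dissociation genes, 7 rose, 1 fell and 11 did not pass, with 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.11e-05; adjusted p = 0.237 with an estimated correlation; fry adjusted p = 0.132). Ier3, Fosl2 and Klf2 rose by 2.83, 1.56 and 2.32. All rises in these 5 lists held under the 3 other scalings. The growth factor list turned down and lost its call with a filter at a TPM of 5 (camera adjusted p = 0.400). Rescaling without mitochondrial and top genes ended the calls of the growth factor and immediate early lists (camera adjusted p = 0.329 and 0.206).

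Markers of non-parenchymal and infiltrating cells rose in liver. All 14 liver endothelial markers measured rose, among them Lyve1, Kdr and Cdh5 by 3.07, 2.66 and 2.58. All 7 markers of quiescent stellate cells that passed the filter on low TPM, of 10 listed, rose, among them Hgf, Lrat by 2.25 and Colec11 by 2.79. Of 13 Kupffer cell markers, 12 rose and 1 did not pass, among them Marco by 2.31, Vsig4 by 2.21 and C1qb by 2.46. All 8 monocyte and monocyte-derived macrophage markers that passed that filter, of 16 listed, rose, with Gpnmb, Lgals3 and Trem2 up by 3.66, 3.45 and 2.81. All 4 neutrophil markers that passed it, of 12 listed, rose, among them S100a9, S100a8 and Retnlg, the last by 2.71. The medians of these 5 lists, in this order, were 2.58, 2.63, 1.93, 2.85 and 3.95 (camera adjusted p = 1.25e-18, 2.84e-11, 1.16e-11, 1.63e-11 and 5.19e-06; adjusted p = 0.202, 0.131, 0.237, 0.177 and 0.215 with an estimated correlation). Of the 12 Kupffer cell rises 11 held under the 3 other scalings, as did all rises of the other 4 lists, although rescaling without mitochondrial and top genes ended the call of the neutrophil list as a whole (camera adjusted p = 0.166). Among the 3 measured red blood cell genes 1 fell and 2 did not pass, and liver CCl4 replicate 2 held 397.9 TPM of Hba-a2 against 1.26 and 4.41 TPM in the other CCl4 libraries.

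**Figure D3:**
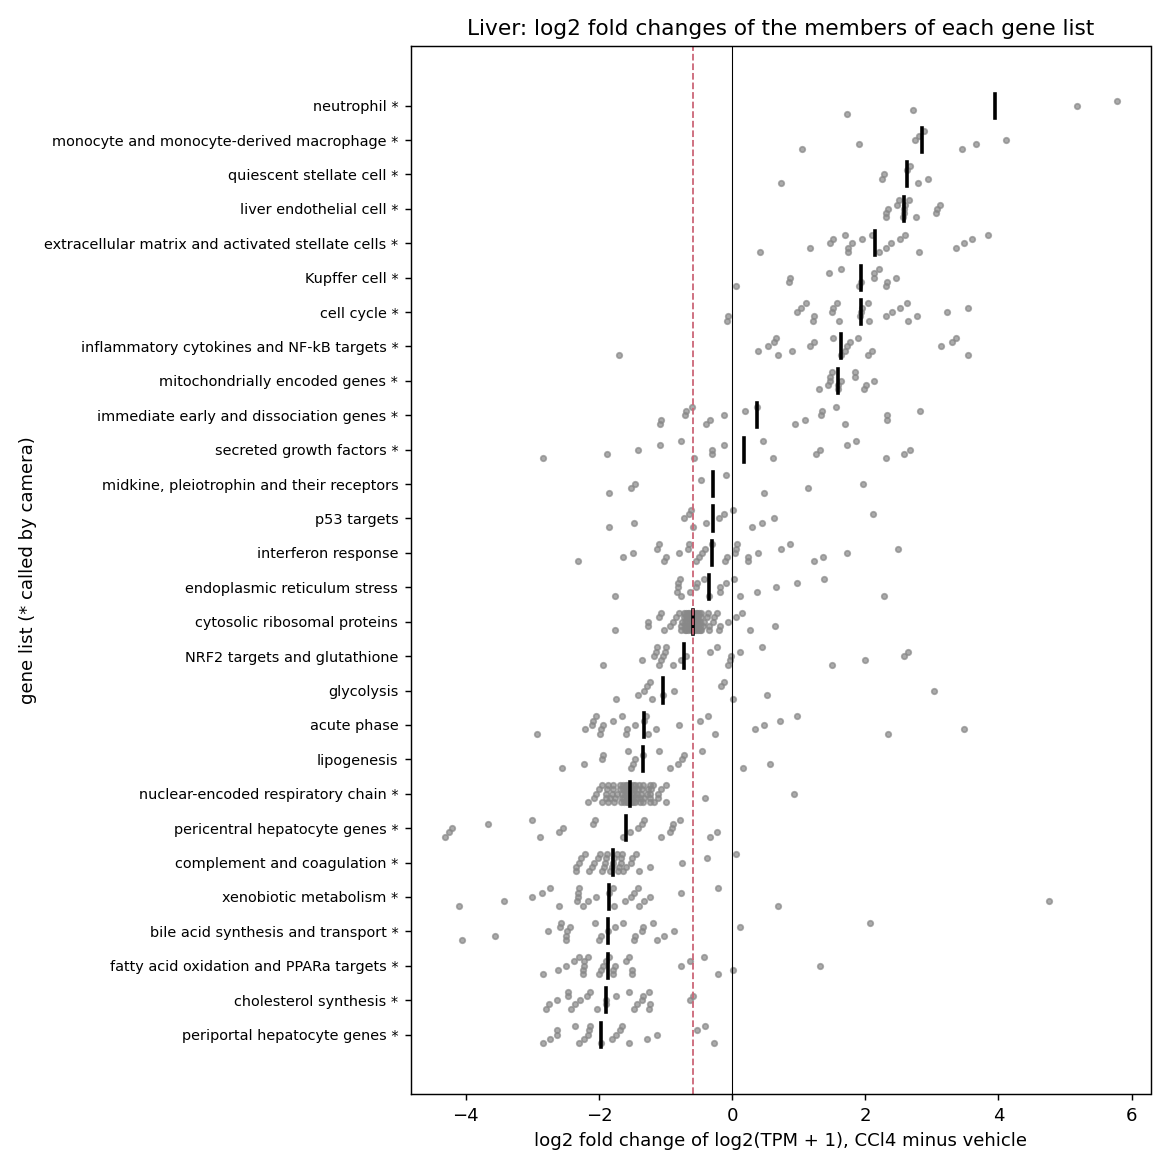
Log2 fold change in liver, CCl4 minus vehicle, of each measured member (grey points) of the gene lists tested, with the list median (black bar), the median of all genes (red dashed line, -0.59) and an asterisk for lists called by camera. Median changes run from 3.95 for neutrophil markers to -1.97 for periportal genes.

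Camera called 19 of 28 liver lists, 11 higher and 8 lower. None passed with an estimated correlation (smallest adjusted p = 0.131), and fry called 19, 10 higher and 9 lower (smallest adjusted p = 0.0022). The other 9 lists were not called. Of 17 lipogenesis genes 10 fell and 7 did not pass (camera adjusted p = 0.248). Of 27 acute phase genes 2 rose, 17 fell and 8 did not pass, with 18 lower adjusted over the list alone (camera adjusted p = 0.550). Among NRF2 and glutathione genes 4 rose and 9 fell of 24, among p53 targets 2 rose and 4 fell of 14, and among interferon response genes 6 rose and 9 fell of 29 (camera adjusted p = 0.154, 0.205 and 0.0505). Of 21 genes of endoplasmic reticulum stress 4 rose and 3 fell, 2 and 1 adjusted over the list alone, and of 13 glycolysis genes 2 rose and 8 fell (camera adjusted p = 0.0645 and 0.875). Of 8 measured genes of midkine, pleiotrophin and their receptors 2 rose and 3 fell, with 4 lower adjusted over the list alone (camera adjusted p = 0.215). For the last 6 lists camera's direction was up although median and mean were below 0. Of 77 cytosolic ribosomal protein genes 1 rose, 13 fell and 63 did not pass, 0 and 2 adjusted over the list alone, with a median of 0.00 relative to all genes (camera adjusted p = 0.728). All rises in these 9 lists held under the 3 other scalings. Of the falls, only 1 lipogenesis and 2 acute phase genes held. Without CCl4 replicate 2 camera called the endoplasmic reticulum stress, interferon and NRF2 lists higher (adjusted p = 0.0119, 0.0391 and 0.0308), and without vehicle replicate 2 the first pair of them (0.0313 and 0.0203). Without CCl4 replicate 3 it called the interferon list higher and the ribosomal protein list lower (0.00620 and 0.0164). Camera also called the acute phase list lower without a filter on low TPM (adjusted p = 0.00453). It did so under rescaling without mitochondrial and top genes and without mitochondrial genes and copies (0.00815 and 0.0101). The ribosomal protein list was called lower without that filter and in the fit over all 12 libraries (camera adjusted p = 9.92e-07 and 0.0237). Too few members were measured to test 7 lists: fetal liver (1 of 1 rose), dendritic cell (1 of 1 rose), B and plasma cell (1 of 2 rose), cholangiocyte (2 rose and 1 fell of 3), red blood cells, and T and natural killer cells with 0 members measured.

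Mdk (ENSMUSG00000027239) was near the lower limit in liver. It was listed at 0 in all 3 vehicle libraries and at 0.87, 0.83 and 0.27 TPM in the CCl4 libraries, a difference of 0.71 in log2(TPM + 1) (exact permutation p = 0.1, n = 3 per group). The size of that difference depended on the settings. It was 2.79 and 0.18 with pseudocounts of 0.1 and 5, and 1.94 without mitochondrial genes and copies in the total. Mdk failed the filter on low TPM, and without that filter limma's adjusted p was 0.0233, with 0.00759 to 0.0521 over the settings run without it. Pleiotrophin, Ptn, was listed at 0 in all liver libraries except 1 CCl4 library at 0.01 TPM, and the receptor gene Ptprz1 at 0 in all 6. Cx3cr1 was at 0.01, 0.01 and 0 TPM with vehicle and at 0.45, 2.06 and 0.44 TPM with CCl4 (exact permutation p = 0.1, n = 3 per group). The midkine receptor genes Lrp1 and Sdc4 fell by 1.52 ± 0.31 and 1.85 ± 0.37, the albumin gene Alb by 1.75 ± 0.29, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 1.48 ± 0.50. Without mitochondrial genes and copies in the total, the changes of Lrp1 and Cyp7a1 turned to 0.16 and 0.10, and those of Sdc4 and Alb, at -0.16 and -0.04, lost their calls. Cyp7a1, whose groups overlap (exact permutation p = 0.2, n = 3 per group), also lost its call under median-ratio scaling and quantile normalization (-0.78 and -0.70) and without vehicle replicate 1 or CCl4 replicate 1 (-1.02 and -1.04). The collagen gene Col1a1 rose by 1.81 ± 0.27 to 2.81 ± 1.69 TPM.

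**Figure D4:**
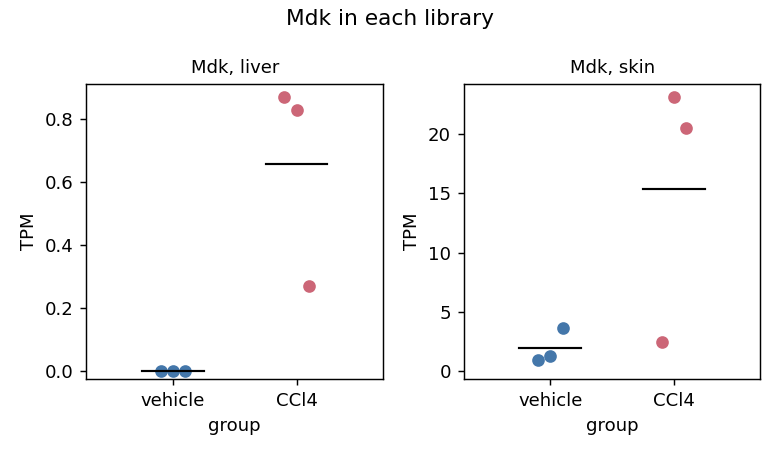
TPM (y axis, linear, 1 scale per panel) of Mdk in the vehicle and CCl4 libraries (x axis) of liver and skin, with points for the 3 libraries and a bar for their mean. Mdk in liver is 0 in the vehicle libraries and at most 0.87 TPM with CCl4, while in skin it reaches 23.2 TPM.

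In the skin libraries, labelled as CX3CR1+ cells, MHC class II and macrophage transcripts had lower values after CCl4 and ribosomal protein transcripts slightly higher ones, but no single gene passed. All 16 MHC class II genes, which serve antigen presentation, had negative changes, with a median of -2.60 (camera adjusted p = 1.39e-15; adjusted p = 0.623 with an estimated correlation). The transactivator Ciita was at 8.79 ± 1.54 TPM with vehicle and 1.83 ± 1.68 with CCl4, and H2-DMb1 and H2-DMa had log2 changes of -3.25 ± 1.15 and -3.02 ± 1.08. All 18 dermal macrophage markers had negative changes, with a median of -2.93 (camera adjusted p = 1.17e-13; adjusted p = 0.623 with an estimated correlation), among them Fcrls at -4.08 ± 1.43, Adgre1 (F4/80) at -3.18 ± 1.31 and Ccl8 at -3.68 ± 1.66. CCl4 replicate 3 had far lower means of both lists than the other libraries, at 2.62 and 1.86 in log2(TPM + 1), against 7.67 and 6.91 in CCl4 replicate 1 and 6.85 and 7.08 in CCl4 replicate 2. Without it the medians were -1.19 and -1.07 (camera adjusted p = 8.13e-15 and 5.95e-07). Of its 10 most abundant genes 7 encode proteins of the cornifying epidermis, among them Lce3c, named after its values were seen, at 32417.6 TPM, against 1754.6 in vehicle replicate 3 and at most 2.87 in the other 4 libraries. Its mean of the keratinocyte list was 4.71, against 5.38 to 6.79 in the other libraries. Of 78 cytosolic ribosomal protein genes 77 had positive changes, with a median of 0.40, among them Rpl27 at 0.88 ± 0.49 and Rplp0 at 0.76 ± 0.45 (camera adjusted p = 5.33e-11; adjusted p = 0.623 with an estimated correlation).

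**Figure D5:**
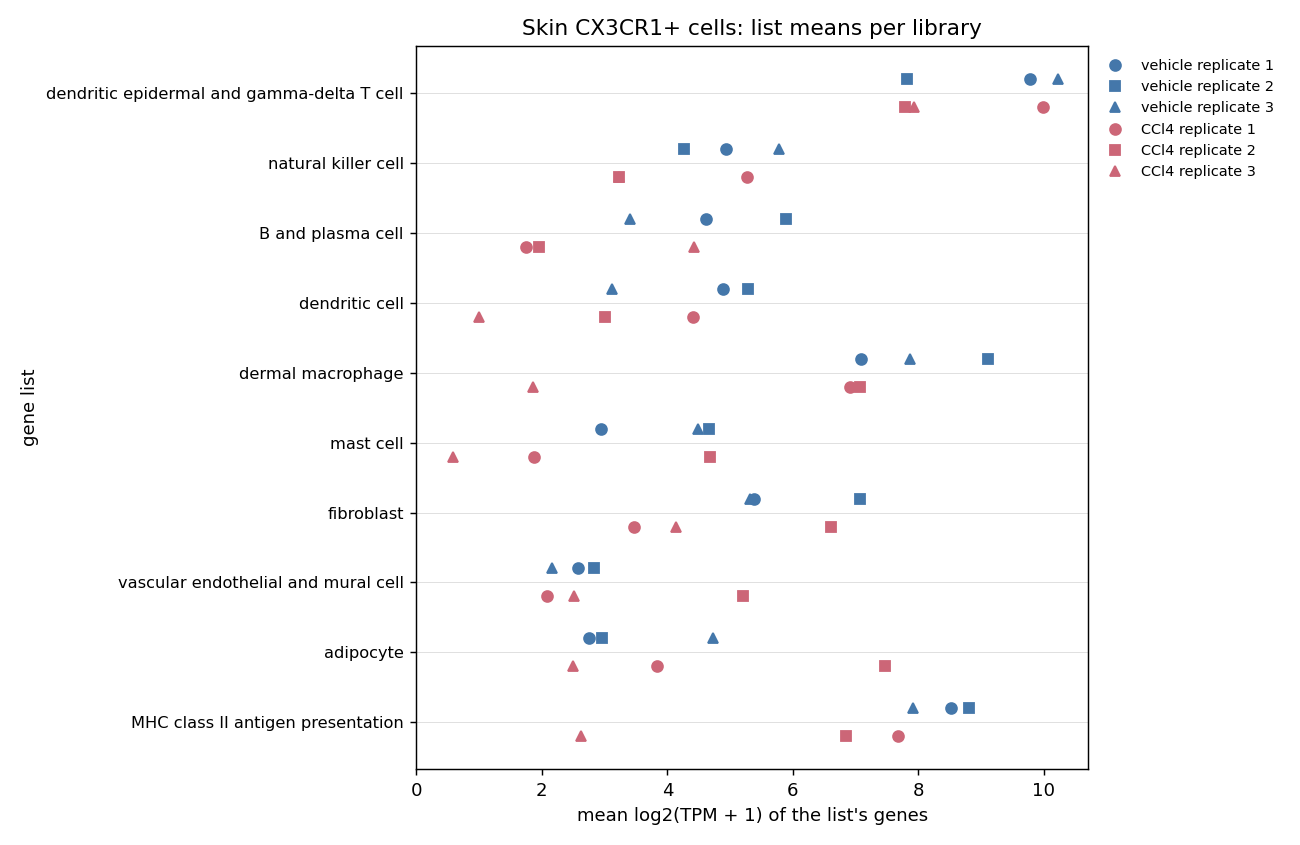
Mean log2(TPM + 1) (x axis) of the genes of 10 lists (y axis) in each skin library, blue for vehicle and red for CCl4, with the replicate given by the marker shape. CCl4 replicate 3 is lowest for the MHC class II and dermal macrophage lists, at 2.62 and 1.86, and CCl4 replicate 2 is highest for the adipocyte list, at 7.47.

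Limma called 0 of 13767 genes in skin (smallest adjusted p = 0.222). Unadjusted p was under 0.05 for 288 genes, where 688 are expected by chance, robust eBayes also called 0, and groups did not overlap for 727 genes, 5.28% of those tested, where chance gives 10%. In 1 fit over all 12 libraries 1 unnamed gene was called, ENSMUSG00002076476, at 70.0, 31.7 and 25.2 TPM with vehicle and listed at 0 in all CCl4 libraries. The lowest p among positive changes belonged to Sprr2d, a cornified envelope gene, at 6.12, 1.85 and 5.11 TPM with vehicle and 43.9, 24.1 and 64.8 with CCl4. Also among the lowest were Lce1l, Lce1a2, Kprp, Cdsn, Cst6 and Sprr2e, genes of the outer epidermis, at 3.48, 3.41, 2.63, 2.64, 2.09 and 3.04. The lowest p among negative changes belonged to Marco, a scavenger receptor, at 23.2, 18.5 and 9.12 TPM with vehicle and 3.87, 0.67 and 0 with CCl4. Clec4g, Nxpe5, Slamf9, the chemokine receptor Ccr2, Dcstamp, Cd226 and Cd209e were at -2.50, -2.60, -2.87, -2.77, -3.21, -3.06 and -3.81.

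Camera called 19 of 36 skin lists, 5 higher and 14 lower, none of them with an estimated correlation (smallest adjusted p = 0.623) or by fry (smallest adjusted p = 0.635). Immune and stromal markers besides macrophages had negative changes: all 9 dendritic cell, all 7 mast cell, all 6 natural killer cell, all 4 B and plasma cell and all 14 fibroblast markers, and 10 of 11 markers of dendritic epidermal and gamma-delta T cells. Their medians were -1.05, -1.66, -1.03, -1.86, -0.72 and -0.72 (camera adjusted p = 0.000275, 0.00156, 0.00204, 0.0104, 0.000996 and 0.0222; adjusted p = 0.623 for the first 4 lists and 0.683 for the last pair with an estimated correlation). Examples were Itgax at -1.95 ± 0.80, the mast cell carboxypeptidase Cpa3 at -2.85 ± 1.41, Klrb1c at -1.41 ± 0.72, Cd79b at -1.58 ± 0.84, Col1a1 at -2.89 ± 1.18 and Klrk1 at -1.29 ± 0.73. Changes were negative for 12 of 18 genes of alternative macrophage activation, 22 of 28 of phagocytosis and lysosome, 31 of 32 of the interferon response, 21 of 27 inflammatory cytokines and NF-kB targets, 22 of 28 cell cycle genes and all 12 mitochondrially encoded genes (camera adjusted p = 0.00396, 0.000275, 0.000607, 0.0200, 0.000127 and 0.000607; adjusted p = 0.683, 0.683, 0.683, 0.780, 0.623 and 0.683 with an estimated correlation). Among them Retnla was at -2.57 ± 0.99, Tyrobp at -2.24 ± 0.98, Ccl12 at -3.44 ± 1.75, Top2a at -2.06 ± 0.62 and mt-Co2 at -1.14 ± 0.64.

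Besides the ribosomal proteins, 4 skin lists were higher by camera. Changes were positive for 19 of 24 NRF2 and glutathione genes, 66 of 80 nuclear-encoded respiratory chain genes, 8 of 10 vascular endothelial and mural markers and all 6 adipocyte markers. Their medians were 0.42, 0.22, 0.74 and 1.23 (camera adjusted p = 0.00291, 0.00204, 0.0114 and 0.0222; adjusted p = 0.683, 0.780, 0.683 and 0.683 with an estimated correlation). Gsta2 was at 1.45 ± 0.69, Atp5g1 at 0.72 ± 0.67, Egfl7 at 1.68 ± 1.21 and the adipocyte lipid-binding gene Fabp4 at 1.96 ± 1.42. The MHC class II, dermal macrophage, cell cycle, phagocytosis, dendritic cell and ribosomal protein lists kept their calls whichever library was left out.

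Single skin libraries decided the other calls. CCl4 replicate 2 held 3926 TPM of Fabp4 and 268 TPM of Egfl7, against at most 118 and 24.9 in the other libraries. Without it the adipocyte and vascular lists turned down (camera adjusted p = 0.797 and 0.612), and the epidermal T cell, natural killer cell, B cell and respiratory chain lists lost their calls (0.612, 0.0900, 0.0520 and 0.0788). Without CCl4 replicate 3 the interferon and inflammatory lists turned up (camera adjusted p = 0.0263 and 0.00102) and the NRF2 list down (0.762). The mitochondrially encoded, alternative activation, respiratory chain, epidermal T cell and mast cell lists then lost their calls (0.732, 0.690, 0.536, 0.150 and 0.0501). Without CCl4 replicate 1 the fibroblast, B cell and mast cell lists lost theirs (camera adjusted p = 0.784, 0.239 and 0.0760). Without vehicle replicate 1 the inflammatory, epidermal T cell, adipocyte and respiratory chain lists did (0.242, 0.236, 0.110 and 0.0858). Without vehicle replicate 2 the respiratory chain list turned down (0.465), and the adipocyte and inflammatory lists lost their calls (0.186 and 0.0661). Without vehicle replicate 3 the epidermal T cell list turned up (0.795), and the natural killer cell, NRF2, mast cell, mitochondrially encoded, vascular, alternative activation and B cell lists lost their calls (0.424, 0.269, 0.182, 0.139, 0.0923, 0.0827 and 0.0827).

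The remaining 17 skin lists tested were not called: itch mediators (camera adjusted p = 0.699), midkine, pleiotrophin and their receptors (0.544), cholesterol synthesis (0.532), p53 targets (0.142), endoplasmic reticulum stress (0.437), glycolysis (0.227), immediate early genes (0.860), monocytes (0.0800), neutrophils (0.860), T cells (0.101), Langerhans cells (0.988), keratinocytes (0.542), hair follicle and sebaceous gland (0.121), Schwann cells (0.619), skeletal muscle (0.0673), red blood cells (0.142) and hepatocytes (0.544). The melanocyte list had 1 measured member, whose change was -0.16 ± 0.65. Median, mean and camera direction differed in sign for the endoplasmic reticulum stress, itch, neutrophil, Langerhans cell and keratinocyte lists. With 1 library left out, camera called 11 of these lists in 1 case or more: without CCl4 replicate 1 T cells (0.00837), without CCl4 replicate 2 red blood cells, monocytes and Schwann cells (4.10e-06, 0.000639 and 0.0186). Without CCl4 replicate 3 it called muscle, keratinocytes, immediate early genes, hair follicle and endoplasmic reticulum stress (3.63e-06, 0.000149, 0.000252, 0.00758 and 0.0263). Without vehicle replicate 1 it called hair follicle, cholesterol synthesis, monocytes, endoplasmic reticulum stress and muscle (8.70e-05, 0.00559, 0.0141, 0.0152 and 0.0331), and without vehicle replicate 2 T cells, red blood cells, monocytes and p53 targets (2.52e-05, 0.00621, 0.0374 and 0.0485).

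Mdk in skin was at 0.93, 1.24 and 3.64 TPM with vehicle and at 2.43, 23.2 and 20.5 with CCl4, a log2 change of 2.16 ± 0.87 (exact permutation p = 0.2, n = 3 per group). Ptn, Lrp1 and Sdc4 were at -1.32 ± 1.28, -0.76 ± 0.80 and -0.49 ± 1.13, and Csf1r, Cd207, Mrc1 and Il1b at -2.63 ± 1.22, -2.10 ± 1.44, -3.14 ± 1.44 and -3.69 ± 1.99. Cx3cr1 itself, at 3.91, 0.27 and 0.91 TPM with vehicle and 5.28, 0 and 0.28 with CCl4, and Ptprz1, at 0.80, 2.86 and 0.08 against 0.92, 0.62 and 0.11 TPM, failed the filter. The values thus leave in doubt how much of the RNA came from cells that express Cx3cr1. Keratinocyte and fibroblast lists had means of 4.71 to 6.79 and 3.47 to 7.07 in the 6 libraries. The dermal macrophage list had a mean of 1.86 in CCl4 replicate 3 and of 6.91 to 9.10 in the other libraries.

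The effect of CCl4 differed between liver and skin for 20 of 9255 genes tested in both, 14 of them with a lower effect in skin and 6 with a higher one. Anxa2 had a log2 change of 4.38 in liver and -0.16 in skin, a difference of -4.54 ± 0.48 (adjusted p = 0.00361). Top2a, at 2.53 and -2.06, differed by -4.58 ± 0.56 and Marco, at 2.31 and -3.07, by -5.37 ± 0.82, and Mup19, at -9.62 and 2.04, differed by 11.67 ± 1.50. Among lists common to both tissues, a test chosen after their values were seen, fry found differences for cell cycle (median difference, skin minus liver, -2.56), monocyte and monocyte-derived macrophage (-3.00), cytosolic ribosomal protein (0.97), nuclear-encoded respiratory chain (1.76), mitochondrially encoded (-2.33) and cholesterol synthesis genes (2.01), with adjusted p = 0.00258, 0.0137, 0.00896, 0.0320, 0.0381 and 0.0400. With an estimated correlation, the adjusted p of these lists was 0.0218, 0.0400, 0.133 for the mitochondrially encoded genes and 0.359 for the other 3. The median differences became -4.34 for cell cycle, -4.83 for monocyte, -0.75 for ribosomal protein, 0.052 for respiratory chain and 0.42 for cholesterol synthesis genes once mitochondrial genes and copies were left out of the total. The ribosomal protein list thus changed sign, and the respiratory chain and cholesterol lists lost their calls (fry adjusted p = 4.78e-06, 0.00270, 0.00503, 0.947 and 0.580). With an estimated correlation only cell cycle then passed (adjusted p = 0.00605), and monocyte markers did not (adjusted p = 0.197). Only 22 of 35 listed cell cycle genes and 8 of 16 listed monocyte markers passed the filter in both tissues. Members near 0 with vehicle in liver passed only if high with CCl4, so the differences of both lists may be overstated.

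Across genes, which are not independent replicates, the log2 changes in both tissues had a Pearson's r of -0.164 (jackknife SE 0.161) and a Spearman's rho of -0.135. Without skin CCl4 replicate 3 they were -0.0206 and 0.000163, and without skin vehicle replicate 2 they were -0.0834 and 0.00704. Of 961 genes higher in liver, 367 had a positive change in skin, 38.2% against 49.5% of all genes. Of 4498 genes lower in liver, 2089 had a negative change in skin, 46.4% against 50.5% of all genes. The number of genes whose effects differed was 649 under rescaling without mitochondrial and top genes, with 7 higher in skin and 642 lower, and 66 without a filter, with 47 higher and 19 lower. It was 4 without any 1 of the 3 liver vehicle libraries, 6, 9 and 233 without liver CCl4 replicates 1, 2 and 3 (in the last case 166 higher and 67 lower), 9, 5 and 419 without skin vehicle replicates 1, 2 and 3 (in the last case 240 higher and 179 lower), and 322 (190 higher and 132 lower) and 73 without skin CCl4 replicates 1 and 2. Tissue, assay and mouse strain changed together, and with 0 genes called in skin an overlap of called genes could not be tested.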

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

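The test of genes for a difference between tissues was planned, whereas the test of lists for such a difference and the tests of explanations below were chosen after the results were seen. The effect of CCl4 differed between liver and skin CX3CR1+ cells, by the test of the difference itself, for 20 genes. Among the genes named, the effect in skin minus that in liver was -4.54 for Anxa2, -4.58 for Top2a, -5.62 for Clec4g, -5.50 for Mmp12, -3.24 for Ccna2, -5.37 for Marco, -2.68 for Aurkb and 11.67 for Mup19. By the same kind of test the effects differed for 6 lists, with median differences of -2.56 for cell cycle, -3.00 for monocyte and monocyte-derived macrophage, 0.97 for cytosolic ribosomal protein, 1.76 for nuclear-encoded respiratory chain, -2.33 for mitochondrially encoded and 2.01 for cholesterol synthesis genes. With an estimated correlation only the first pair passed (adjusted p = 0.0218 and 0.0400), and the others did not (adjusted p = 0.359, 0.359, 0.133 and 0.359 in that order). The filter on low TPM kept 22 of 35 cell cycle and 8 of 16 monocyte genes in both tissues. Genes near 0 with vehicle in liver passed it only if high with CCl4, so the differences of that pair may be overstated. Without mitochondrial transcripts and copies in the total, the differences of the respiratory chain and cholesterol lists, at 0.052 and 0.42, lost their calls (fry adjusted p = 0.947 and 0.580), that of the ribosomal protein list turned to -0.75, and the monocyte list no longer passed with an estimated correlation (adjusted p = 0.197). Chance cannot be excluded for the count of genes. Of 100 splits drawn within the tissues, 15 called at least 20 genes, the real one among them. The highest other split called 2809. That split kept the liver libraries grouped by treatment and set skin vehicle replicates 1 and 2 with CCl4 replicate 1 against the rest, which points to a structure of the skin samples. Of the 8 other splits that kept the liver libraries grouped by treatment, 5 called at least 20 genes. Among these, 1 grouped skin by treatment too, with its direction turned, and called 27. Of the 91 other splits that also regrouped the liver libraries, 9 called at least 20 genes, at most 953.

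Most called liver genes were lower with CCl4, and so were 8 lists, 7 of hepatocyte functions and the nuclear-encoded respiratory chain, by camera with the preset correlation, none of which passed with an estimated one (adjusted p = 0.661 to 0.662). A larger share of the total taken by mitochondrial transcripts and their copies could account for the direction of most calls, since 5.91% of called genes were lower once those transcripts were left out, and for the fall of respiratory chain members in TPM, 76 of which were lower before and 0 after. These counts do not measure how much it explains. Leaving those transcripts out moved all genes nearly alike, their median going from -0.59 to 0.85. The larger share is argued against as the whole cause for the other 7 lists: of their 182 members 159 were lower before, and 55 lower and 30 higher after. A larger share moves other genes by about 1 factor per library, so it would hardly move the respiratory chain list relative to all genes. Against that, the list's mean changed by -0.98 (SE 0.18) relative to that of all genes before and by -0.79 (SE 0.15) after. The latter lay 5.26 SE from 0, beyond the limit of 2.78 SE. The larger share is thus argued against as the cause of that list's place relative to all genes. A bias by transcript length or GC content is argued against as the whole cause. Once such a trend was taken out of each library, the means of all 8 lists relative to all genes still changed. The changes were -1.37 to -0.87, 3.64 SE or more from 0. A lower share of RNA from hepatocytes as 1 uniform cell type would lower their markers alike. Against that, 8 of 12 hepatocyte markers, from -4.32 to -1.64, lay further from their median than 2.78 SE, a limit not adjusted for the 12 markers. Loss of hepatocytes of 1 zone could lower markers unequally and stays open: Cyp2e1, at -4.32, is also a pericentral gene. The mean change of the pericentral list minus that of the periportal list was -0.18 (SE 0.06, exact permutation p = 0.1), 3.07 SE from 0. The medians of the 2 lists, at -1.59 and -1.97, ran the other way. What raised the mitochondrial share, whether RNA quality, the way the RNA was selected or the treated tissue itself, was not tested and stays open, as do changes within hepatocytes.

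Most of the fall of these lists in TPM was lost with the rescaling: the median of the 7 lists went from -1.83 to -0.17, that of the respiratory chain from -1.53 to 0.15 and that of all genes from -0.59 to 0.85. In place of the test of the 7 lists, camera on the rescaled values was run first. Rescaling by about 1 factor per library moves all genes of a library together, so camera could not decide on the lists' fall in TPM. The test of the markers likewise replaced a comparison of pericentral genes with hepatocyte markers, which had given a difference of 0.20 (SE 0.06, exact permutation p = 0.1). The test of the respiratory chain list relative to all genes and the tests of the means of the skin lists below were added once the other tests had been read, as was that of length and GC content, in place of a count of camera calls. The liver has too few splits, 10, for a share under 0.05: the real one called 6377 genes and the highest other 2, with 1 split reaching the real value, and it called 19 lists and the highest other 21, with 4 splits reaching the real value.

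MHC class II and dermal macrophage lists were lower with CCl4 in skin by camera with the preset correlation, but with an estimated one neither passed (adjusted p = 0.623 for each), and their means changed by -2.70 (SE 1.59) and -2.74 (SE 1.81) between libraries. Without skin CCl4 replicate 3 they changed by -1.15 (SE 0.46) and -1.03 (SE 0.76), within the limit of 3.18 SE for 5 libraries, so that 1 library stays open as the cause. A shift shared by the libraries numbered 1, of which each group holds 1, would add equally to both groups and gives no difference, and with both left out the medians were -3.39 and -4.32. Fewer macrophages among the collected cells and lower MHC class II expression within them cannot be told apart, since both lists changed alike (difference 0.040, SE 0.62, exact permutation p = 0.9) and no count of cells is at hand. A response of the skin cells to CCl4 stays open, untested.

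In skin too the 10 splits are too few for a share under 0.05. The real split called 0 genes with limma, with 288 at an unadjusted p under 0.05 and 0 with robust eBayes, so 10 of 10 splits reached its value. The highest other called 689, for vehicle replicates 1 and 2 with CCl4 replicate 1 against the rest, which points to a structure of the samples. For lists the real split called 19 and the highest other 22, with 4 splits reaching the real value.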

How the results depend on the processing

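Most alternatives were chosen before the data were examined; rescaling without mitochondrial genes and their copies, the batch term and leaving out both skin libraries numbered 1 were chosen after seeing the data. For named liver genes, 1396 of 1445 values under the alternatives kept direction and side of the threshold, 44 lost the call and 5 reversed; for named skin genes, none of them called, 1699 of 1706 kept direction and 7 reversed. For liver lists 422 of 501 values kept direction and side of the threshold, 29 gained a call, 27 lost it and 23 reversed; for skin lists 578 of 713 did, 24 gained a call, 68 lost it and 43 reversed. Depth is unknown, so the limit it sets on genes of low TPM cannot be given. The labels do not say whether replicates of the same number pair. In liver their deviations from the group means correlated at -0.04, 0.08 and 0.07, against -0.11 to 0.08 for different numbers. In skin the values were 0.59, 0.09 and 0.35, against -0.51 to 0.16, so pairing stays open there. A replicate block gave 716 skin genes at an unadjusted p under 0.05, in place of 288. Except where a smaller or larger set of genes or libraries, an added threshold, or a shift of all genes by the scaling changes a value by construction, the cause was not tested. Mdk in liver has no value under quantile normalization, the filter at a TPM of 5 and the fit over 12 libraries among these alternatives.

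Without a filter on low TPM, 2007 liver genes were higher, the NRF2 and endoplasmic reticulum stress lists turned down (adjusted p = 0.952 and 0.792), Mdk in liver was called with a change of 0.71, and 66 genes differed between tissues. With a filter at a TPM of 5, 4084 liver genes were called, 321 of them higher, 11 genes differed between tissues, and the acute phase, growth factor and ribosomal protein lists in liver and the Langerhans cell list in skin turned direction (adjusted p = 0.514, 0.400, 0.0511 and 0.932). With a minimum log2 change of 1, 3707 liver genes were called, 2873 of them lower. With a pseudocount of 0.1, 176 genes differed between tissues.

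The scalings moved the split of liver calls into higher and lower. Median-ratio scaling gave 2159 higher and 2210 lower, turned the glycolysis list down (adjusted p = 0.833) and the ribosomal protein list up (adjusted p = 0.00973), and gave 56 genes that differed between tissues. Quantile normalization gave 1826 higher and 2507 lower, reversed the lipogenesis, acute phase and ribosomal protein lists in liver (adjusted p = 0.980, 0.130 and 1.82e-21) and the Langerhans cell list in skin (adjusted p = 0.781), and gave 51 genes that differed. Rescaling without mitochondrial and top genes gave 6497 higher and 495 lower, reversed the ribosomal protein list (adjusted p = 5.37e-07), and moved Lrp1 to 0.074 and Cyp7a1 to 0.018, with 649 genes that differed. Rescaling without mitochondrial genes and their copies gave 6922 higher and 435 lower, reversed the ribosomal protein list (adjusted p = 1.19e-07), and moved Atp5s to 0.050, Lrp1 to 0.16 and Cyp7a1 to 0.10, with 548 genes that differed.

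With a replicate block, 6493 genes were called in liver and 0 in skin, 345 differed between tissues, 160 higher and 185 lower in skin, and the ribosomal protein list in liver and the neutrophil and Langerhans cell lists in skin reversed (adjusted p = 0.679, 0.848 and 0.657). In 1 fit over all 12 libraries, 1736 liver genes were called, 334 higher and 1402 lower, the glycolysis list reversed (adjusted p = 0.685), and 1 skin gene was called. Named liver genes that lost their call there included Col3a1, Col1a1, Cxcl2, C1qb, Fosl2, Atp5s, Alb and Cyp7a1. With library number 1 as a batch term, 131 genes differed between tissues. With both skin libraries numbered 1 left out, 62 did, and the itch, neutrophil, Langerhans cell and keratinocyte lists reversed (adjusted p = 0.869, 0.717, 0.869 and 0.262). With an estimated correlation, 0 liver lists and 0 skin lists were called by camera, and fry called 0 skin lists and reversed the Langerhans cell list (adjusted p = 0.939). In liver, fry called 19 lists and reversed NRF2, p53, endoplasmic reticulum stress, interferon, midkine and glycolysis (adjusted p = 0.616, 0.409, 0.688, 0.345, 0.409 and 0.0564).

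Leaving out 1 library at a time gave 4874 to 7607 called genes in liver and 0 in skin, 11 to 20 skin lists, the fewest without vehicle replicate 3, and 4 to 419 genes that differed between tissues, the fewest without any 1 liver vehicle library and the most without skin vehicle replicate 3. Adjusted p of lists that reversed in at least 1 such case ran, in liver, from 0.774 to 0.915 for glycolysis and from 0.0164 to 0.997 for ribosomal proteins. In skin they ran from 0.00559 to 0.975 for cholesterol synthesis, 1.24e-05 to 0.762 for NRF2, 0.0152 to 0.983 for endoplasmic reticulum stress, 3.73e-08 to 0.0263 for interferon, 2.72e-06 to 0.242 for inflammatory, 0.0827 to 0.732 for midkine, 0.159 to 0.921 for itch, 0.0656 to 0.850 for glycolysis, and 2.06e-11 to 0.536 for respiratory chain genes. For immediate early genes they ran from 0.000252 to 0.921, and for cell types from 0.273 to 0.897 (neutrophils), 2.52e-05 to 0.807 (T cells), 6.31e-10 to 0.795 (epidermal T cells), 0.801 to 0.993 (Langerhans cells), 0.000149 to 0.993 (keratinocytes), 0.000505 to 0.612 (vascular cells), 0.0186 to 0.921 (Schwann cells), 8.89e-06 to 0.797 (adipocytes), 4.10e-06 to 0.795 (red blood cells) and 0.0745 to 0.993 (hepatocytes). Log2 changes of skin genes that changed sign ran from -0.058 to 3.51 for Nqo1, -0.83 to 0.26 for Ighm, -0.33 to 3.57 for Cfd, -0.44 to 2.00 for Adipoq and -1.75 to 0.35 for Sdc4.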

Other observations

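All tests below were chosen after the results were seen. The rises of the marker lists were compared between liver cell types. Compared with Kupffer cell markers, the mean log2 change was higher by 2.14 ± 0.64 for neutrophil, 1.11 ± 0.34 for monocyte and 0.62 ± 0.27 for quiescent stellate cell markers (exact permutation p = 0.1 each, the smallest possible) and by 0.93 ± 0.43 for endothelial markers (exact permutation p = 0.2). The first pair of differences lay 3.32 and 3.30 SE from 0, beyond the limit of 2.78 SE, and the stellate and endothelial ones 2.27 and 2.15 SE. Of the listed markers 4 of 12 neutrophil, 8 of 16 monocyte and 7 of 10 stellate cell ones passed the filter on low TPM, against all 13 Kupffer cell ones. Markers near 0 with vehicle passed only if high with CCl4, so the rises of those incomplete lists may be overstated.

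The 8 largest falls in liver were 7 Mup genes and Elovl3, which are known to be higher in male than in female mouse liver. A hypothesis is that CCl4 lowered male-biased transcripts as a group. Of 7 other such genes tested 6 fell, and their median of -3.26 lay at percentile 0 of 10000 random lists matched on vehicle TPM, 95% of which had medians between -1.90 and -0.48. The data are compatible with that hypothesis, and the median stayed at -2.00 without mitochondrial genes and their copies in the total. The random lists were not matched on expression in hepatocytes, and hepatocyte lists fell too: the 7 lists of hepatocyte functions had a median of -1.83, or -0.17 when rescaled in that way. The percentile thus does not separate male-biased genes from hepatocyte genes at large. The 4 female-biased genes tested, among them Acot3 of the fatty acid oxidation list, lay at percentile 82.9 with 0 called, too few to say whether such genes moved the other way. Longer lists were run first and gave percentiles of 0 and 90.4, and the sex of the mice is not given in the sources used here.

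Of the 8 skin genes with the lowest p among positive changes, 4 were Lce or Sprr genes of the cornified envelope. A hypothesis is that transcripts of cornifying keratinocytes were higher with CCl4 in the collected cells. Of the 22 other Lce and Sprr genes measured 21 had positive changes, with a median of 2.09, but the rotation test fry, a relative of permutation tests, did not call them (p = 0.240), so the test could not decide. Without CCl4 replicate 3 the changes were positive for 15 of the 22, with a median of 0.96.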
